A study of Homo sapiens with 10 samples.

How the data were processed

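The study measured mRNA in human peripheral blood monocytes that had been separated by elutriation, a way of sorting blood cells by size and density, and then cultured. Per the labels, 5 arrays hold untreated control cells and 5 hold cells given leukotriene B4 (LTB4) at 50 nM for 30 minutes. Total RNA was isolated with an RNeasy Mini column kit and turned into biotin-labelled cRNA, per the labels' protocols. The series also names leukotriene D4, and cells treated with it were not analysed here.

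The values deposited by the authors are linear signal intensities, 1 for each of 54675 probe sets on each array, computed with MAS5 per the submitters' processing notes, which give no version. MAS5 is the Affymetrix method that turns the probes of a set into 1 background-corrected signal and scales each array. The mean signal after trimming 2% of probe sets at each end was 100.01 on each of the 10 arrays, and the table held 0 missing values. The median signal per array lay between 16.6 and 20.4, and 44.5% to 49.2% of probe sets had a signal under 16. No detection calls were used here, so low signals have no stated background, and the precision of each value is limited by the number of arrays.

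Probe sets were named from the platform's gene annotation. It gave 1 gene to 41091 probe sets and several genes to 1801, and 11721 probe sets were not listed. The 62 control probe sets were left out of all tests. Gene identifiers were looked up in a RefSeq gene table, which held the identifier of 41037 of the probe sets with 1 gene and changed 0 symbols. Probe sets with several genes or no listed gene were tested but not named. Genomic positions of probes were not used here.

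The signals were used as scaled by the authors, as log2(signal + 16). The offset of 16 damps the noise of dim probe sets, and log2 changes and folds are on this scale, which understates the change of genes with low signal. Of 54613 probe sets, the 27306 with the highest mean over all arrays were tested; the dimmest of these had a mean signal of 16.5. limma 3.58.1 in R 4.3.3 fitted treatment plus the replicate number as a block, with lmFit and eBayes (trend = TRUE), and p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 5%. Adjusted p-values of single probe sets in the text come from this fit, and errors of log2 changes are its standard errors.

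The replicate number was used as a block because the series' design text calls control and treated cells matched and the titles number both groups from 1 to 5. The labels do not say whether the numbers stand for donors, cultures or days. The deviations of same-numbered arrays from their group means correlated at 0.44 to 0.66, and those of differently numbered arrays at -0.31 to 0.06. The p-values of the blocked fit measure the spread of the differences within these pairs, moderated over probe sets. They leave out the spread between replicates.

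A set of 25 gene lists, with 626 distinct genes, was fixed before the data were examined. Each gene was represented by its brightest tested probe set, which gave 515 measured genes, and 67 list genes had no probe set of their own. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, and again with a correlation estimated for each list. They were also tested with the directional test of fry, which asks whether the members of a list moved together up or down. It does not compare the list with other genes. Counts of members that passed were also taken with p-values adjusted over the list alone. Genes named in the text follow a rule set at the same time. The rule takes the 12 largest rises and the 12 largest falls among probe sets of 1 gene that passed in the same direction in 5 of 5 pairs. It adds up to 4 members of each list that passed, or the 2 with the largest change where 0 passed, and 16 genes of leukotriene biology and monocyte activation. Other genes are named after their values were seen, where this is stated.

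RNA quality was followed by the log2 ratio of 3' to 5' control probe sets of GAPDH and ACTB, and other blood cells by the mean of marker lists on each array. Both were compared between groups by an exact two-sided sign-flip permutation test over the 5 pairs, whose smallest possible p is 0.0625.

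The fit was tested on simulated data with the means and pair effects of the 27306 probe sets, of which 200 were changed in each of 20 simulations. Normal noise was drawn without correlation between genes, from the variances that limma had already moderated. The simulated data therefore follow the model of the fit more closely than the arrays may. The fit recovered 55.4% of changes of 0.5 log2 units, 97.8% of changes of 1 and 100% of changes of 2, and 7.54% of all calls were of probe sets that had not been changed. The list test called the list shifted by 0.5 in 20 of 20 simulations and the same list without a shift in 0 of 20. Other lists passed at a mean of 0.2 per simulation. Every member of the shifted list, that of chemokines, was moved, while in the data its mean log2 change was 0.17. The simulation therefore does not test lists in which few members moved, nor lists with correlated members. In the data the estimated correlation was 0.32 for immediate early genes and 0.83 for ribosomal proteins.

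The alternatives tried were a fit without the block, quantile normalization, median centring, no offset, an offset of 64, no filter on signal, a filter keeping the upper 30% of probe sets, eBayes without its trend or with robust estimation, array weights, averaging the probe sets of a gene, a paired test without moderation, and leaving out each pair in turn. Files were read with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.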

Results

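The data are signals of 54675 Affymetrix probe sets on 10 arrays of cultured human monocytes, 5 from untreated cells and 5 from cells exposed to LTB4 at 50 nM for 30 minutes. LTB4 is a lipid mediator that draws leukocytes to sites of inflammation and acts through G protein-coupled receptors. The series concerns how monocytes respond to LTB4 and to leukotriene D4, and the arrays described here address the response to LTB4. Each LTB4 array was compared with the control array of the same number. The arrays were close to each other, with log2 correlations from 0.954 to 0.984, and the highest of these was between the control and LTB4 arrays of replicate 3.

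After 30 minutes of LTB4, immediate early genes rose most. FOSB, a subunit of the AP-1 transcription factor, rose from a signal of 7.71 ± 5.90 to 480 ± 172 (SD, n = 5 each). EGR3, a zinc finger transcription factor, rose from 71.9 ± 44.0 to 720 ± 137. The nuclear receptor genes NR4A1 and NR4A2, in their most changed probe sets, rose from 37.7 ± 30.2 to 264 ± 92.6 and from 75.6 ± 21.0 to 360 ± 123. The falls were smaller, and those of JUN and ZFP36L2 were shared by several probe sets of the gene.

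In total 456 probe sets passed a 5% false discovery rate in limma, 251 higher and 205 lower with LTB4. They represent 165 named genes with a higher and 125 with a lower probe set, and 95 of the 456 have no single listed gene. A change of at least 1.5-fold was reached by 124 of the higher and 83 of the lower probe sets, and one of at least 2-fold by 40 and 3. The median log2 change was 0.58 among the higher and -0.52 among the lower. The direction was the same in 5 of 5 pairs for 246 of the higher and 205 of the lower. These probe sets were called in a fit blocked on the same pairs, so this is no separate evidence. Over all tested probe sets 13.9% moved in 1 direction in 5 of 5 pairs, where chance gives 6.25%. The count depended on the pairing and the variance model, and was 50 without the replicate block, 94 without the trend, 262 without the signal filter, 298 with probe sets of a gene averaged and 0 in a paired test without moderation, which had 3281 probe sets at an unadjusted p under 0.05 against 3816 in limma. It was 267, 268, 266 and 300 without replicate 1, 2, 3 and 4.

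**Figure D1:**
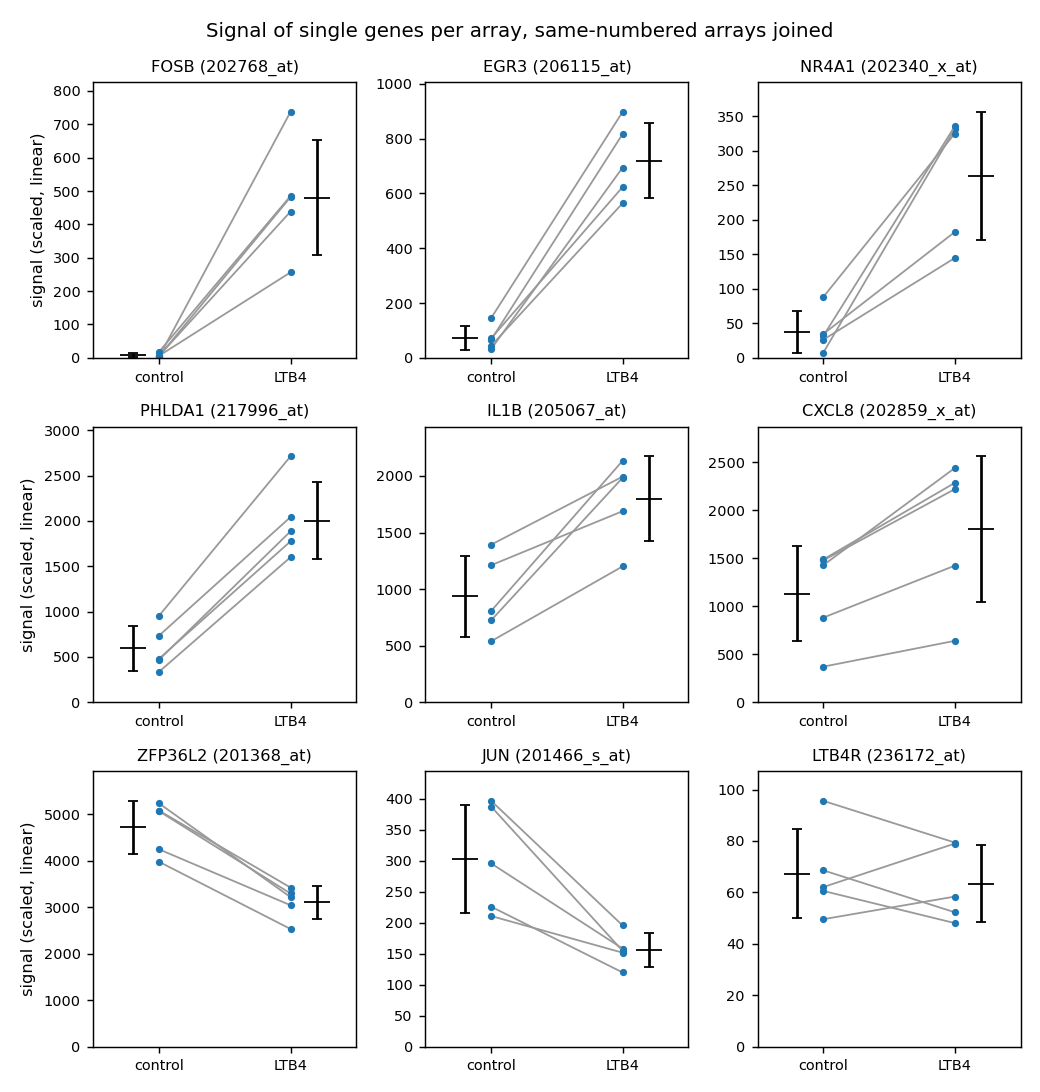
Signal (linear, as scaled by the authors) of single genes on each of the 5 control and 5 LTB4 arrays. Grey lines join arrays of the same number and black bars give mean and SD; FOSB, EGR3, NR4A1, PHLDA1, IL1B and CXCL8 were higher and ZFP36L2 and JUN lower with LTB4 in 5 of 5 pairs, while LTB4R was higher in 2 of 5.

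The list of immediate early transcription factors also holds other immediate early genes, such as MCL1. Of its 28 measured genes, 21 rose, 1 fell and 6 did not pass (24 rose and 2 fell when adjusted over the list alone). FOSB rose by 4.34 ± 0.19 log2 units (adjusted p = 5.71e-07) and EGR3 by 3.17 ± 0.15 (adjusted p = 5.78e-07). The 5 control signals of FOSB lay under 18.1, near the floor of the array, so the size of its rise is set largely by the offset. NR4A1 rose by 2.48 ± 0.25 in its brightest probe set and by 1.14 in its other tested one. NR4A2 rose by 1.69 ± 0.15 in its brightest probe set. Its 2 other tested probe sets rose by 1.61 and by 2.01 ± 0.19. ATF3, a stress-responsive factor, rose by 1.30 ± 0.07 and the survival gene MCL1 by 1.03 ± 0.07 in its brightest probe set, with its other 4 also higher. Of the 2 other tested probe sets of ATF3 1 rose and the other, a dim one, had -0.07 ± 0.28; of those of EGR1 1 rose and the other had 0.58 ± 0.17 and did not pass. EGR1 rose from 521 ± 177 to 1064 ± 369 (SD, n = 5; adjusted p = 0.0148 in limma) and FOS by 0.60 ± 0.08 (adjusted p = 0.00278), each higher in 5 of 5 pairs. Without replicate 2 the change of EGR1 was 0.83 with an adjusted p of 0.0754. JUN, another AP-1 subunit, fell: its brightest probe set changed by -0.69 ± 0.08. The list as a whole was shifted upwards in camera (adjusted p = 3.36e-38; adjusted p = 0.0821 with an estimated correlation).

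Feedback regulators of MAP kinase and G protein signalling formed a further group, in which 8 of 26 measured members rose and 0 fell (8 and 1 when adjusted over the list alone; 9 and 2 at an unadjusted p under 0.05 in limma). PHLDA1 rose from 596 ± 247 to 2002 ± 428 (SD, n = 5), a log2 change of 1.79 ± 0.09, and its 5 other tested probe sets rose too. SPRY2, an inhibitor of receptor tyrosine kinase signalling, rose by 1.19 ± 0.12, RASGEF1B by 1.04 ± 0.14 and TRIB1 by 1.04 ± 0.08. DUSP1, a MAP kinase phosphatase, rose by 0.35 ± 0.06 (adjusted p = 0.00697) in its brightest probe set, whereas its other 2 tested probe sets had values of -0.45 and -0.15 that did not pass. With the probe sets of DUSP1 averaged the change was -0.08 and the call was lost (adjusted p = 0.737). The list was shifted upwards (camera adjusted p = 4.30e-04; adjusted p = 0.0821 with an estimated correlation), while its median log2 change was 0.01.

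Among cytokine and chemokine genes a minority passed, IL1B, TNF and CCL2 among the rises. Of 22 measured cytokines and growth factors 5 rose and 1 fell (8 and 1 over the list alone), and of 17 chemokines 3 rose and 1 fell (5 and 2 over the list alone). IL1B, which encodes interleukin 1 beta, rose by 0.99 ± 0.13 in its brightest probe set, from 935 ± 354 to 1800 ± 372 (SD, n = 5), and by 1.20 ± 0.14 in its other. TNF rose by 0.96 ± 0.08 and OSM by 0.72 ± 0.10, and TNFSF14 fell by 0.68 on the log2 scale. The other tested probe set of TNFSF14 had -0.14 ± 0.14 and did not pass, and with both averaged the change was -0.41 and the call was lost. Among chemokines CCL2, which attracts monocytes, rose by 0.89 ± 0.07, CCL4 by 0.73 ± 0.10 and CXCL8, which attracts neutrophils, by 0.68 ± 0.05. CXCL9 changed by -0.53 ± 0.12 (adjusted p = 0.0471), a call that was lost without replicate 1, 2, 3 or 4 (adjusted p from 0.113 to 0.155). Both lists were shifted upwards in camera, cytokines with an adjusted p of 4.55e-05 and chemokines with 4.07e-04, and each had an adjusted p = 0.0821 with an estimated correlation.

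Of 29 measured NF-kB targets and regulators 4 rose and 0 fell (8 and 0 over the list alone; 9 and 3 at an unadjusted p under 0.05 in limma). CD83, an activation marker, rose by 0.93 ± 0.09, the survival gene BCL2A1 by 0.83 ± 0.11, the inhibitor NFKBIA by 0.51 ± 0.10 (adjusted p = 0.0216) and NFKBID by 0.39 ± 0.08. The calls of NFKBIA and NFKBID were each lost without replicate 1, 2, 3 or 4, with log2 changes from 0.40 to 0.52 and from 0.32 to 0.43 and adjusted p-values from 0.0602 to 0.0780 and from 0.0545 to 0.129. The list was shifted upwards in camera (adjusted p = 4.92e-04, and adjusted p = 0.328 with an estimated correlation). Its median log2 change was 0.05, and fry gave an adjusted p of 0.184.

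In the leukotriene and eicosanoid pathway 4 of 24 measured genes rose and 0 fell (also 4 and 0 over the list alone; 5 and 1 at an unadjusted p under 0.05 in limma), and these 4 belong to prostanoid synthesis, prostaglandin E2 reception and reception of platelet-activating factor. PTGER2 rose by 0.87 ± 0.09, PTGS2 by 0.63 ± 0.12, PTGER4 by 0.48 ± 0.06 and PTAFR by 0.31 ± 0.06. The leukotriene genes themselves did not pass. The LTB4 receptor gene LTB4R had a signal of 67.3 ± 17.2 in control and 63.5 ± 14.9 in LTB4 arrays (SD, n = 5), a log2 change of -0.07 ± 0.13. The cysteinyl leukotriene receptor gene CYSLTR1 had a change of 0.07 ± 0.07, and the synthesis genes ALOX5, ALOX5AP and LTA4H had 0.12 ± 0.06, 0.12 ± 0.05 and 0.09 ± 0.06. CYSLTR2 lay below the signal filter (9.34 ± 6.34 and 9.82 ± 7.79), and LTB4R2 had no probe set of its own. Without replicate 1, 2 or 4 the call of PTAFR was lost (adjusted p from 0.0787 to 0.113), as was that of PTGS2 without replicate 1, 2, 4 or 5 (adjusted p from 0.0661 to 0.101). The list was shifted upwards in camera (adjusted p = 0.00164; adjusted p = 0.169 with an estimated correlation).

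Of 25 measured chemoattractant receptors 6 rose and 1 fell (9 and 2 over the list alone). HCAR3, a hydroxycarboxylic acid receptor, rose by 1.59 ± 0.10, from 103 ± 123 to 349 ± 384 (SD, n = 5), the wide spread coming from replicate 3. The sphingosine 1-phosphate receptor gene S1PR3 rose by 0.76 ± 0.14, the complement receptor gene C3AR1 by 0.55 ± 0.06, and the nucleotide receptor gene P2RY13 fell by 0.45 on the log2 scale. The call of S1PR3 was lost without replicate 1, 2 or 4 (adjusted p from 0.0523 to 0.0741) and that of P2RY13 without replicate 1, 3 or 4 (adjusted p from 0.0608 to 0.0794). The list was shifted upwards in camera (adjusted p = 2.37e-04, and adjusted p = 0.254 with an estimated correlation). Its median log2 change was 0.06, and fry gave an adjusted p of 0.0616.

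**Figure D2:**
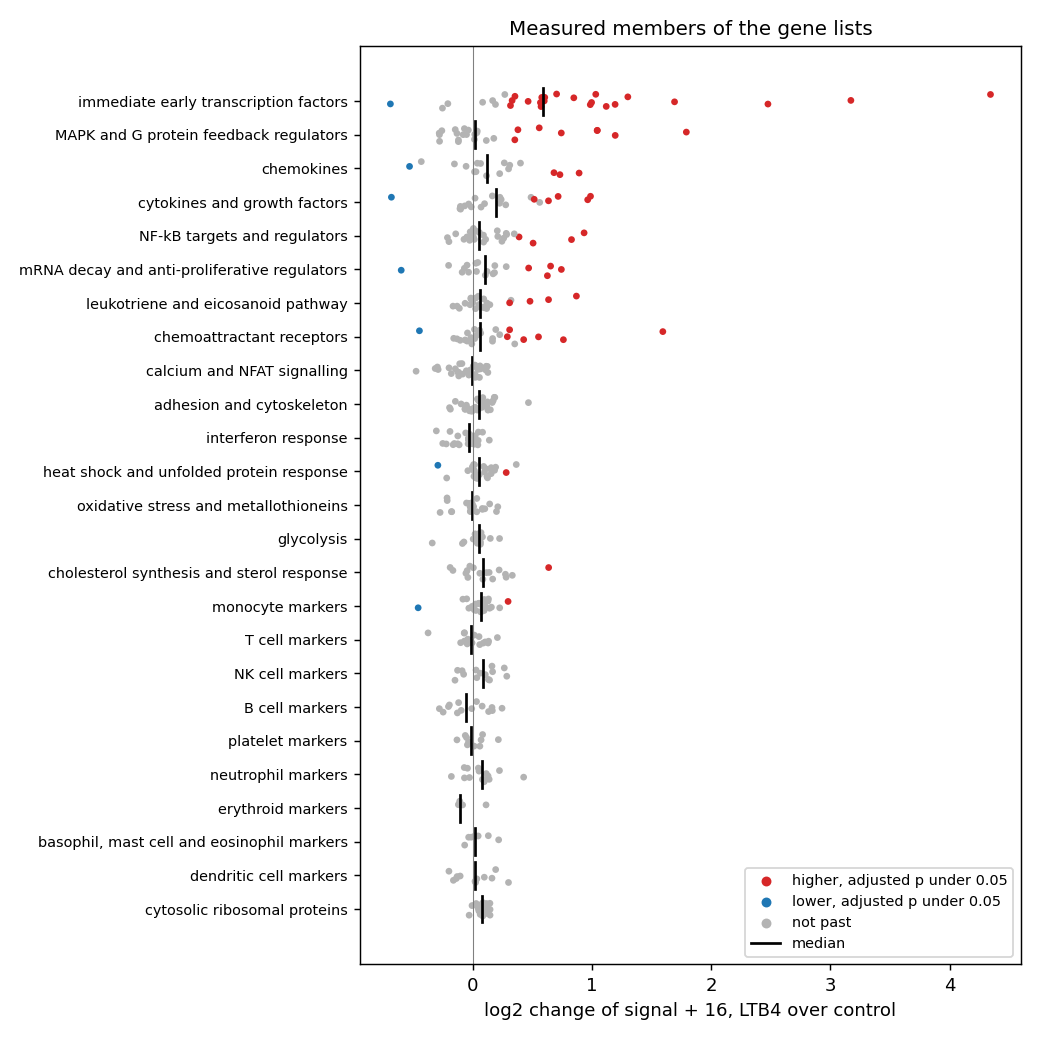
Log2 change of signal + 16 between LTB4 and control arrays for the measured members of 25 gene lists, 1 point per gene and a black line at the median of each list. Red and blue points passed a 5% false discovery rate. Of the immediate early list 21 of 28 genes rose, against 0 of 32 calcium and NFAT genes.

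Regulators of mRNA decay and growth arrest moved both ways, with 4 of 19 higher and 1 lower (7 and 2 over the list alone). ZFP36, which encodes the mRNA-destabilising protein tristetraprolin, rose from 2047 ± 160 to 3229 ± 300 (SD, n = 5), PPP1R15A rose by 0.74 ± 0.08 and SERTAD1 by 0.63 ± 0.08. ZFP36L2, a gene of the same family, fell from 4718 ± 567 to 3102 ± 347 in its brightest probe set (log2 change -0.60 ± 0.05, adjusted p = 3.51e-05), and its other 2 probe sets fell by 0.82 and 0.71. The list was shifted upwards in camera (adjusted p = 0.00114; adjusted p = 0.0821 with an estimated correlation).

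The largest falls among probe sets of 1 gene included JUN (-0.86 ± 0.10 in its most changed probe set) and ZFP36L2. The others came from probe sets with mean control signals between 29.5 and 198. SMG9 changed by -1.20 ± 0.18, from 44.4 ± 7.18 to 11.2 ± 7.96 (SD, n = 5), LCAT by -0.98 ± 0.19 and SCARB2 by -0.98 ± 0.19. JRK changed by -0.89 ± 0.15, ANKRD13D by -0.87 ± 0.09 and CLNS1A by -0.84 ± 0.17. TMEM165 changed by -0.79 ± 0.17, ZFYVE16 by -0.78 ± 0.15, ERN2 by -0.75 ± 0.15 and CEPT1 by -0.73 ± 0.12. The mean LTB4 signals of SMG9, LCAT, SCARB2 and TMEM165 lay under 16, so the offset largely sets the size and order of these falls: SMG9 had -2.41 with no offset and -0.53 with an offset of 64, and LCAT -1.90 and -0.44. LCAT had no other tested probe set, and no other tested probe set of the remaining 9 genes passed. Leaving out a single replicate ended the call of TMEM165 (any of the 5), LCAT, SCARB2, CLNS1A, ZFYVE16 and ERN2 (4 of 5 replicates) and CEPT1 (replicate 2), with adjusted p-values from 0.0519 to 0.147. Among the largest rises LONRF1 rose by 1.22 ± 0.09 with its other probe set also higher, whereas ANKRD28 (1.22 ± 0.15) and S100A10 (1.21 ± 0.09) had other tested probe sets that did not pass.

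The remaining lists held few or no members that passed. Of 25 heat shock and unfolded protein response genes, XBP1 rose by 0.28 ± 0.06 and HSPA6 fell by 0.29 on the log2 scale, both calls being lost when single replicates were left out (4 and 3 of the 5). Of 17 cholesterol genes INSIG1 rose, by 0.64 ± 0.06. These lists had camera adjusted p-values of 0.00438 and 0.00114, and adjusted p = 0.315 and adjusted p = 0.0821 with an estimated correlation. No member passed among 32 calcium and NFAT genes (0 higher and 5 lower at an unadjusted p under 0.05 in limma; PLCB2 had -0.48 ± 0.18 and GNA11 -0.32 ± 0.13), 34 adhesion and cytoskeleton genes (7 and 2; VASP had 0.47 ± 0.11 and WAS -0.20 ± 0.08), 29 interferon response genes (0 and 5; IRF7 had -0.25 ± 0.07 and IFITM3 -0.31 ± 0.10), 23 oxidative stress genes (3 and 2; MT1F had -0.28 ± 0.13 and MT1E -0.22 ± 0.09) or 20 glycolysis genes (2 and 0; ENO2 had -0.34 ± 0.17 and SLC2A3 0.22 ± 0.07, and 1 of the 2 other probe sets of SLC2A3 rose). Of all 27306 tested probe sets, 3816 had an unadjusted p under 0.05 in limma. Counts of this kind, here and for the other lists, are to be read against that share. Without replicate 5, PLCB2 had -0.73 (adjusted p = 0.0165) and VASP 0.59 (adjusted p = 0.0173). PLCB2 and VASP had no other tested probe set. Other tested probe sets of WAS, MT1F and MT1E went the other way and those of GNA11 went both ways, with none past the threshold. Those of GNA11 ranged from -0.18 to 0.44, and those of WAS, MT1F and MT1E had 0.23, 0.05 and 0.06. The camera adjusted p of these 5 lists was 0.393, 0.0182, 0.0835, 0.852 and 0.0835. The upward shift of the adhesion list was lost with an estimated correlation (adjusted p = 0.501), and had an adjusted p of 0.123 without replicate 2 and 0.110 without replicate 3. The 34 ribosomal protein genes had a median log2 change of 0.07 with 0 members past the threshold (3 higher and 0 lower at an unadjusted p under 0.05 in limma). Their upward shift in camera (adjusted p = 5.32e-05) had an adjusted p = 0.594 with an estimated correlation, and the median was -0.01 after quantile normalization. The largest values among them were RPS25 0.14 ± 0.05 and RPS7 0.14 ± 0.07. Of all 25 lists 13 passed in camera at the preset correlation and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05.

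The marker means and RNA quality ratios differed little between the groups. In control arrays the mean log2(signal + 16) of monocyte markers was 11.7 to 11.9. It was 7.14 to 8.09 for T cell markers and 6.06 to 7.45 for NK cell markers. Signal of T and NK cell markers thus varied between replicates, and the values do not show in which cells a change arose. Of 24 monocyte markers MS4A7 rose by 0.30 ± 0.05 and CEBPA, a myeloid transcription factor, fell by 0.46 on the log2 scale, while CD14 had 7696 ± 598 and 9003 ± 818 (SD, n = 5; adjusted p = 0.0618 in limma). The list's upward shift in camera (adjusted p = 0.00114) had an adjusted p = 0.495 with an estimated correlation and was turned to a downward one by quantile normalization (adjusted p = 0.844). The mean of the monocyte markers differed by 0.05 log2 units between LTB4 and control arrays (exact sign-flip p = 0.312, 5 pairs). No member passed among the T cell, NK cell, B cell, platelet, neutrophil, erythroid, basophil or dendritic cell markers, for which limma gave 0, 0, 1, 0, 2, 0, 0 and 2 members at an unadjusted p under 0.05. Their list means differed by -0.01, 0.07, -0.03, 0.01, 0.07, -0.07, 0.04 and 0.01, with exact sign-flip p-values from 0.125 to 0.938. The members with the largest log2 changes were CD7 -0.38 ± 0.21 and CD8A 0.21 ± 0.17 (T cell), XCL1 0.28 ± 0.18 and KLRD1 0.26 ± 0.15 (NK cell), CD79A -0.28 ± 0.11 and CD22 -0.25 ± 0.16 (B cell) and GP1BA 0.21 ± 0.18 and TREML1 -0.13 ± 0.18 (platelet). For the other 4 lists they were CEACAM3 0.43 ± 0.15 and CEACAM8 0.22 ± 0.13 (neutrophil), BPGM -0.12 ± 0.08 and AHSP -0.12 ± 0.13 (erythroid), GATA2 0.22 ± 0.10 and ENPP3 0.13 ± 0.19 (basophil) and BATF3 0.30 ± 0.20 and NRP1 -0.20 ± 0.10 (dendritic cell). The camera adjusted p of these lists lay between 0.111 and 0.917. The 2 other tested probe sets of KLRD1 had -0.15 and -0.0008 and those of GATA2 -0.004 and 0.09, with none past the threshold. The other tested probe set of CD7 had -0.004 and that of CD79A -0.01. For CEACAM3 the other 2 had 0.09 and 0.50, and for NRP1 the other had -0.37, again with none past the threshold. The 3' to 5' log2 ratio differed by -0.01 for GAPDH (exact sign-flip p = 0.938) and by -0.06 for ACTB (exact sign-flip p = 0.750), and by 0.05 and 0.01 without replicate 4. With 5 pairs this two-sided test cannot reach 5%.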

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

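Single arrays far from the other 4 of their group were looked for in 208 groups of 5, made up of the named probe sets, the marker means and the RNA quality ratios; 9 groups had one, and chance gives about 10.4. The tests of replicate 3 were chosen after its values were seen.

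In replicate 3, the signal of HCAR3 was 322 in the control array, against 38.3 to 67.6 in the others, and 1034 in the LTB4 array, against 127 to 200. The control array of replicate 3 also had a CXCL9 signal of 1397, against 77.4 to 133. Both genes were highest in replicate 3 in both groups, so the difference existed without LTB4. A wrong replicate number on an array of the pair is argued against by the deviations of these arrays from their group means. They correlated at 0.66 and matched each other best. An exchange of the control and LTB4 labels within the pair would leave this match in place, so the match cannot judge it. RNA of neutrophils is argued against by the mean of 15 neutrophil markers, which in replicate 3 differed from the other replicates by -0.45 in control and -0.37 in LTB4 arrays. The mean of the interferon response genes was the highest of the 5 in both groups, and lay above the mean of the other 4 by 1.54 in control arrays and 1.35 in LTB4 arrays, where the SD of the others was 0.59 and 0.52; CXCL9 is a classical interferon gamma target. An earlier exposure of these cells to interferon is therefore a candidate explanation for CXCL9, as a hypothesis found and tested on the same arrays. NK cell markers were also highest in replicate 3 (0.82 above the mean of the other 4 in both groups, where the SD of the others was 0.52 and 0.49), and no biological explanation given by the design was tested.

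FOSB had a signal of 18.0 in the control array of replicate 5, against 3.29 to 6.21 in the others. CEACAM3 had 20.7 in the control array of replicate 4, against 43.7 to 53.2. WAS had 1055 in the control array of replicate 2, against 1477 to 1685. CD22 had 7.59 in the LTB4 array of replicate 4, against 33.8 to 40.6. HSPA6 had 389.5 in the LTB4 array of replicate 5, against 827 to 1096. The ACTB 3' to 5' log2 ratio was 0.72 in the control array of replicate 4, against 0.35 to 0.42.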

How the results depend on the processing

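The alternatives for the number of list members past the threshold were chosen after the data were seen, and the others before. The 456 probe sets became 50 (42 higher, 8 lower) without the replicate block, and these 50 were among the 456; the 5% threshold was passed by 262 without the signal filter, 94 without the trend of the variance and 298 (145 higher, 153 lower) with probe sets of a gene averaged. A paired test without moderation called 0 probe sets (lowest adjusted p = 0.0580; 3281 at an unadjusted p under 0.05), where limma called 456. Leaving out each replicate in turn, which also leaves fewer samples, gave 266 to 355. Quantile normalization gave 416 and median centring 403, with 55.8% and 51.6% higher against 55.0%. The share that was higher was 64.5% without the signal filter, 75.5% without the trend and 84% without the block. It lay between 57.5% (without replicate 5) and 69.2% (without replicate 3) when a replicate was left out.

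The 64 list members that passed became 17 without the replicate block, 27 without the trend and 0 without moderation. The 13 lists past the threshold became 0 with an estimated correlation (7 at an unadjusted p under 0.05 in camera) and 7 in fry. Those that fry did not call were the NF-kB, chemoattractant receptor, adhesion, heat shock, monocyte and ribosomal lists. The number of lists without the replicate block was 13. Quantile normalization turned the shift of the monocyte markers (adjusted p = 0.844) and the ribosomal proteins (adjusted p = 0.841), and averaging the probe sets of DUSP1 turned its change to -0.083; the cause was not tested.

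Of 59 named probe sets past the threshold, 42 passed without each replicate in turn, while 59 were lost without moderation, 43 without the replicate block, 30 without the trend, 13 without the signal filter and 13, besides that of DUSP1, with probe sets of a gene averaged. The last 13 were those of ANKRD28, EGR1, PTGER4, MS4A7, CXCL9, TNFSF14, CEPT1, ERN2, ZFYVE16, TMEM165, JRK, SCARB2 and SMG9. CXCL9 had no other tested probe set to average. The call of DUSP1 also ended with averaging, where its change turned to -0.083 (adjusted p = 0.737 in limma). None was lost with quantile normalization, robust estimation, an offset of 64 or, among those it tested, the upper 30% filter. About 44.5% to 49.2% of probe sets had a signal under 16, where changes are compressed by the offset.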

Other observations

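The genes and tests in this part were chosen after their values were seen, except the splits of the arrays. Further single genes, not tested as a group, rose in 5 of 5 pairs: THBD, which encodes thrombomodulin, by 0.96 ± 0.09, the Fc receptor gene FCAR by 0.89 ± 0.07, TREM1 by 0.71 ± 0.06, CD69 by 0.75 ± 0.09 and the cytokine signalling inhibitor SOCS3 by 1.08 ± 0.20. AHR, the aryl hydrocarbon receptor gene, rose by 0.90 ± 0.06, RGCC by 1.06 ± 0.06 and CYTIP by 0.89 ± 0.05.

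Falls with a bright probe set included TENT5A (-0.63 ± 0.09), MYCL (-0.56 ± 0.09), the transcriptional repressor gene PRDM1 (-0.51 ± 0.06), PDK4 (-0.51 ± 0.09) and KCNE3 (-0.39 ± 0.05). The brightest probe sets of 6 of 6 measured GIMAP genes, a family of GTPases of immune cells, had values below 0, also with quantile normalization and median centring. GIMAP7 (-0.46 ± 0.09) and GIMAP8 (-0.34 ± 0.05) passed the threshold, and the median of the 6 was -0.22.

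For some abundant mRNAs a dim probe set rose and the brightest one did not pass. S100A10 had 1.21 ± 0.09 at a control signal of 191 and 0.09 ± 0.06 at 6094. S100A6 had 0.76 ± 0.14 at 50.4 and 0.03 ± 0.07 at 9716. VIM had 0.92 ± 0.14 at 28.3 and 0.13 ± 0.06 at 7971. CD44 had 0.96 ± 0.12 at 153 and 0.18 ± 0.05 at 5905, while a further bright probe set of CD44 rose by 0.27 ± 0.05.

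Falls were shared by other probe sets of the gene less than rises were in size, but about as often in sign. Among genes whose most changed probe set moved by at most 2-fold, the median ratio of the other probe sets' change to the called change was 0.47 for 88 rises and 0.28 for 102 falls. The difference of 0.19 (permutation p = 0.0211) describes the pattern in genes picked for a called change, and so does not decide whether the whole mRNA fell alike for all its probe sets; the other probe sets had the same sign for 81.6% of 103 falls and 84.3% of 102 rises. Noise of dim probe sets also stays open: 93 of the 103 falls lay in the upper 30% by signal and passed when only those were tested, but they had been called on the same arrays. Probe sets on other parts of the gene, or on RNA outside the listed genes, may contribute: 33.2% of the probe sets that fell had no single listed gene, against 10.8% of those that rose and 17.0% of those not called (falls against rises, Fisher's exact test, odds ratio 4.11, p = 6.95e-09), and this stays open because probe positions were not used here.

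JUN and ZFP36L2 fell while 21 of 28 genes of the immediate early list rose. A single faulty probe set is argued against by the 7 tested probe sets of both genes, of which 7 were lower with LTB4 and 5 passed the threshold. The scaling of the arrays is argued against by quantile normalization, after which JUN had -0.70 ± 0.08 (adjusted p = 4.74e-04 in limma) and ZFP36L2 -0.68 ± 0.05. An early end of transcription or a faster decay of these mRNAs may underlie the falls; this is a hypothesis, and arrays at other times, which would test it, were not analysed here.

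The 456 probe sets were set against other splits of the 10 arrays into 5 and 5, in the same blocked fit. Of 100 splits, 1 gave as many, the real one, and the highest of the others gave 5. Most of the others part only 1 or 3 pairs, so they are no like comparison for the real split, which parts 5. Since the numbers pair the samples, the closer comparison is with the 16 splits that part all 5 pairs, of which 1, the real one, gave as many and the highest other gave 0; with 16 splits the share cannot go under 1 in 16.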
